A study of Mus musculus with 90 samples.

How the data were processed

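Gene expression was measured in mouse brain sections with the GeoMx Digital Spatial Profiler, an assay in which probes bound to RNA in a tissue section are released by light from chosen areas of interest (AOIs), collected and counted by sequencing. The probes were those of the mouse Whole Transcriptome Atlas, and the tissue was fixed in formalin, embedded in paraffin and sectioned at 5 µm, per the labels' protocols. Per the labels and the series design, 6 mice exposed to chronic social stress (CSS) and 4 control mice were used. AOIs lay in 5 subregions: the choroid plexus (CP), the motor (MC) and somatosensory (SS) cortex, and the hippocampal fields CA1 and CA3. Each AOI was labelled p16 high or p16 low. p16 is a cell cycle inhibitor encoded by Cdkn2a and used as a marker of senescent cells. How p16 status was assigned to an AOI, and which staining guided it, is not given in the sources used here, so Cdkn2a between p16 high and p16 low AOIs served as a check of the labels and not as a finding. AOIs were placed in matching areas of each animal, per the series design.

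The deposited table holds 1 value for each of 19962 genes and 1 negative control probe in each of 90 AOIs, and 1 further column of values was not used. The values are a signal that the authors scaled so that every AOI had the same median over genes, 22.067, as the values themselves show. The genome build was mm10, per the submitters' processing notes. The read processing tools and their versions are not given in the sources used here. Because each gene value was a whole-number probe count times a factor for its AOI, counts were recovered by dividing by that factor. At least 99.985% of the values of an AOI came out within 0.01 of a whole number, apart from 3 genes whose values were not whole; all were rounded. Recovered totals ran from 184469 to 2098984 counts per AOI, and the median count per gene from 6 to 82. The signal of the negative probe ran from 10.785 to 18.143, and 22.7% of all gene values lay at or below the negative probe of their AOI, so that differences in genes of low signal were poorly measurable. Gene names are those of the file. Of the 19962 genes, 19822 (99.3%) matched a RefSeq gene table of the assembly GRCm38.p6, which is the mm10 build, and coordinates are given on that build.

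The replicate was the animal. Values were taken as log2(signal + 1), so a fold change is on that scale and understates the change of genes of low signal. For comparisons within animals (p16 high against low, CA3 against CA1, CP against the other subregions), the AOIs of an animal were averaged to 1 value per animal and condition, and the mouse was a fixed block in the model. The pairing came from the mouse number in the labels, since both AOIs of a subregion came from the same animal. Deviations of paired high and low AOIs correlated at a median of 0.11 over 41 pairs, with 22 pairs above 0.1. For CSS against control mice, each animal's values were centred within subregion and p16 status on the midpoint of the group means and averaged, so that missing AOIs did not shift an animal. Models were fitted over all genes with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), 2-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Every adjusted p of a gene comes from limma with Benjamini-Hochberg adjustment unless another tool is named.

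For 36 gene lists of 6 to 73 measured genes, fixed before the data were examined and covering brain cell types, hippocampal subfields, synaptic parts, senescence, stress hormone and inflammatory programmes, and housekeeping machinery, a set test was run with camera in limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera compares a list with all other genes. Its form with an estimated correlation, and fry, which tests whether a list moved on balance one way without reference to other genes, were alternatives. Members were also counted with the p adjusted over the list alone. List means per animal were compared with exact 2-sided tests, by sign flips of the animals' differences or by permuting the group labels.

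The comparisons, tests, lists, most other settings and the rule for named genes were set before the data were examined. By that rule Cdkn2a and Cdkn1a were always named. Also named were the 10 highest and 10 lowest log2 fold changes among called genes with the same sign in every animal, or, between groups of mice, with groups that did not overlap. From each list up to 4 members with the smallest p could be named. Where fewer than 5 genes were called, the 5 highest and 5 lowest moderated t values were available and are given as values that did not pass.

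The data were also fitted, as set beforehand, with log2(signal + 10), with genes of mean signal above the median gene alone, quantile normalization, the model without the mouse block, the mouse as a random block over all AOIs, both other set tests, and leaving out each animal in turn. Added after the data had been seen were edgeR 4.0.16 (quasi-likelihood test with TMM scaling, on recovered counts summed per animal, and for CSS against control only on animals with every AOI of the comparison), scaling each AOI to its 75th percentile, the log2 ratio of the gene median to the negative probe (signal over background) as a covariate, and fits with a block for, or within, the 5 animals of deeper and the 5 of shallower recovered counts. The labels name no slide, run or date, so no other batch could be tested. The models were checked on simulated counts of 19962 genes, in which known changes were put into genes with a mean signal above the median gene. In the pooled p16 comparison 29.9% of genes changed 1.25-fold, 91.0% of those changed 1.5-fold and 100% of those changed 2-fold were recovered. For pooled CSS against control the shares were 23.9%, 98.5% and 100%. For CSS against control in CA1 they were 1.49%, 13.4% and 74.2%, and in CP 0%, 4.48% and 66.7%. For the difference of the p16 effect between groups they were 0%, 13.4% and 71.2%, and for CA3 against CA1 7.46%, 64.2% and 98.5%. The simulated noise was drawn for each gene apart, without a structure of the samples shared between genes. The real data held such structure, as other groupings of the mice called up to 2175 genes. The shares may therefore overstate what could be recovered here.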

Results

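Gene expression was profiled in 90 AOIs from the brains of 6 CSS mice and 4 control mice, 46 labelled p16 high and 44 labelled p16 low. With 10 mice, 5 subregions and 2 p16 labels, 100 AOIs were possible and 10 were missing, so that the 20 groups held 3 to 6 AOIs. Mean recovered counts per AOI ran from 310406 in CSS mouse 1170 to 1337914 in control mouse 1175. CSS mice had 624040 ± 280593 counts per AOI (mean ± SD of 6 mice) and controls 826280 ± 424690 (4 mice, exact 2-sided permutation p = 0.376). The gene median stood at 1.53 ± 0.10 times the negative probe in CSS mice and 1.54 ± 0.19 times in controls (exact permutation p = 0.919). Controls held both the highest mouse, 1182 at 1.70, and the lowest, 1175 at 1.30.

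Subregion was the largest source of variation between AOIs. The first principal component carried 48.1% of the variance, with 95.4% of it between subregions, and the second 19.9%, with 81.7% between subregions. The fourth component carried 2.15%, and 68.5% of that lay between mice. The plot of the first components shows the choroid plexus apart from the hippocampus and cortex, with MC and SS mixed and the 2 CA3 AOIs of mouse 1175 near the cortex.

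**Figure D1:**
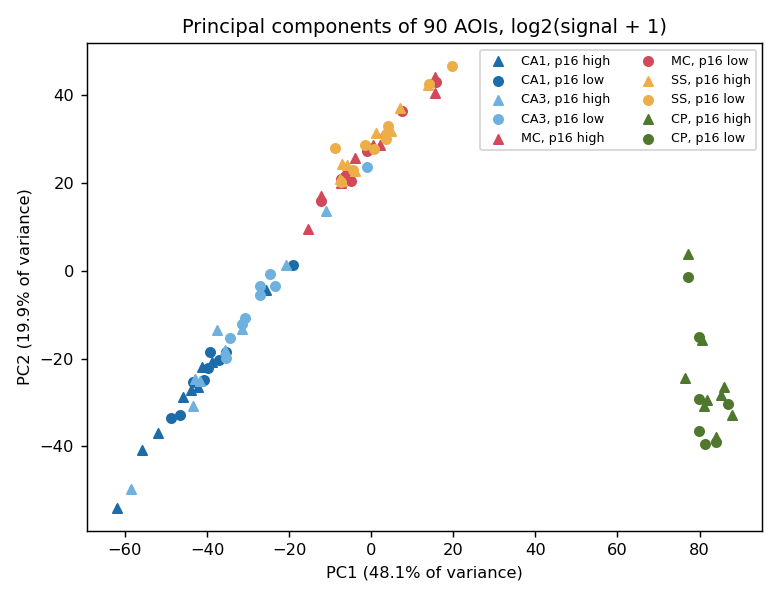
Principal components of log2 signal over 90 AOIs, with subregion and p16 label marked for each AOI. Choroid plexus AOIs lay apart, and those of MC and SS were mixed.

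CA3 and CA1 differed in many genes. Whether CA3 AOIs held tissue of other fields was not tested. Compared with CA1, CA3 AOIs had higher Cpne4 (12.3-fold, log2 fold change 3.62, SE 0.13, mean signal 217 against 16.7 in 10 mice), Ncald (log2 3.40, SE 0.11), Nrip3 (3.31, SE 0.14), Spock1 (3.25, SE 0.10), Prkcd (3.06, SE 0.23), Pcp4 (3.02, SE 0.21), Rph3a (2.92, SE 0.14), Islr2 (2.64, SE 0.17), Grik4 (2.37, SE 0.15) and Amigo2 (2.36, SE 0.26). Several of these encode calcium-binding or calcium-regulated proteins, such as Cpne4, Ncald and Rph3a, and Grik4 encodes a kainate receptor subunit. CA1 AOIs had higher signal of Pou3f1, a POU-domain transcription factor (18.9-fold, CA3 against CA1 log2 -4.24, SE 0.16, mean signal 19.2 in CA3 against 380 in CA1). Also lower in CA3 were Fibcd1 (-3.85, SE 0.15), Ccn3 (-3.64, SE 0.14), the endoplasmic reticulum protein gene Wfs1 (-3.62, SE 0.14), Mpped1 (-3.28, SE 0.13), Tmsb10 (-3.09, SE 0.11), Pex5l (-3.07, SE 0.10), Sertm1 (-3.03, SE 0.12), Doc2b (-3.01, SE 0.12) and Arhgap12 (-2.85, SE 0.11). All 20 genes differed the same way in all 10 mice, as the rule for naming them required, with limma adjusted p from 6.26e-18 to 7.74e-08.

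In all, 2983 genes were called between CA3 and CA1, 798 higher in CA3 and 2185 lower, and 1543 of them had the same sign in every mouse. The balance between higher and lower genes depended on scaling. Quantile normalization called 1397 higher and 1435 lower, and scaling to the 75th percentile 1933 higher and 1306 lower, with the median log2 fold change over all genes moving from -0.02 to 0.13. edgeR called 4221 genes, 1398 higher and 2823 lower. Within the 5 mice of shallower counts 1141 genes were called, 311 higher and 830 lower. When the labels of CA3 and CA1 were swapped within mice, the real assignment called the most genes of 100, and the highest other called 1106.

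All 9 CA1 pyramidal neuron markers were lower in CA3, all 9 passing the test, among them Itpka (-2.76, SE 0.09) and Man1a (-2.59, SE 0.09, camera adjusted p = 4.89e-31, and adjusted p = 0.0025 with an estimated correlation). All 10 CA3 pyramidal markers were higher in CA3 and 9 passed, with Bok at 2.30 (SE 0.10) and Nectin3, a cell adhesion gene, at 1.70 (SE 0.13, camera adjusted p = 1.23e-21, adjusted p = 0.0011 with an estimated correlation). The values of both marker sets in each mouse are drawn in the marker plot. Of 20 astrocyte markers 18 were higher in CA3 and 10 passed, 12 when adjusted over the list alone, among them the glutamate transporter Slc1a2 (1.07, SE 0.11, camera adjusted p = 6.91e-09, adjusted p = 0.0348 with an estimated correlation).

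**Figure D2:**
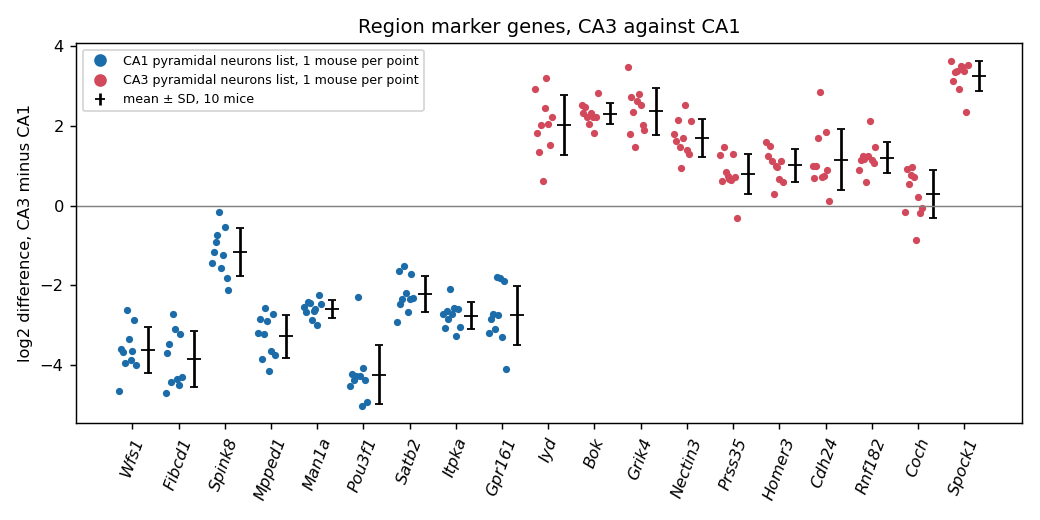
CA3 minus CA1 difference of 9 CA1 markers and 10 CA3 markers in each of 10 mice, on the log2 scale. The CA1 markers were lower and the CA3 markers higher in CA3, and the direction of neither list turned under another scaling.

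Synaptic genes split by side of the synapse. Of 25 genes of the presynaptic vesicle cycle 20 were called higher in CA3 and 1 lower, among them Snap25 of the fusion machinery (1.39, SE 0.09), Rims1 (1.12, SE 0.08) and Syn2 (1.12, SE 0.09, camera adjusted p = 7.75e-21, adjusted p = 0.0917 with an estimated correlation). Of 28 postsynaptic density genes 21 were called lower in CA3 and 1 higher, including the glutamate receptor subunits Grin2a (-1.42, SE 0.09), Grin2b (-1.20, SE 0.09) and Gria1 (-1.06, SE 0.09, camera adjusted p = 1.88e-15, adjusted p = 0.114 with an estimated correlation). Of 22 immediate early genes, which respond to neuronal activity, 10 were called lower and 1 higher in CA3, with Nr4a1 at -1.73 (SE 0.10), Egr1 at -1.60 (SE 0.08) and Arc at -0.98 (SE 0.09, camera adjusted p = 3.49e-05, adjusted p = 0.116 with an estimated correlation). Of 20 oligodendrocyte genes 6 were called higher and 1 lower, with the myelin gene Cnp at 0.70 (SE 0.11, camera adjusted p = 4.69e-06, adjusted p = 0.0917 with an estimated correlation). Without the mouse as a block, 2097 genes were called between CA3 and CA1.

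The choroid plexus expressed its epithelial genes at very high levels. Ttr, which encodes transthyretin, the thyroid hormone carrier secreted by this epithelium, reached a mean signal of 77549 in CP against 36.7 in hippocampus and cortex of the same 9 mice (2057-fold, log2 11.01, SE 0.20). Enpp2, which encodes autotaxin, was 197-fold higher (log2 7.63, SE 0.06). Next came Ecrg4 (6.57, SE 0.12), Igfbp2 (6.35, SE 0.11), which encodes a binding protein of insulin-like growth factors, the growth factor gene Igf2 (6.33, SE 0.10), Col9a3 (6.06, SE 0.10), the channel genes Trpm3 (5.47, SE 0.08), Kcnj13 (5.30, SE 0.11) and Clic6 (5.27, SE 0.12), and Kl, which encodes klotho (5.24, SE 0.10). Neuronal genes were lower in CP: the calmodulin-binding Nrgn (-5.81, SE 0.12, mean signal 47.8 against 2747), Snap25 (-5.72, SE 0.13), Camk2a (-4.76, SE 0.11), Syp (-4.72, SE 0.15), the vesicular glutamate transporter Slc17a7 (-4.70, SE 0.11), Uchl1 (-4.63, SE 0.22), Syn1 (-4.61, SE 0.11), Vsnl1 (-4.49, SE 0.14) and Syt1 (-4.48, SE 0.13). Each of these genes differed the same way in 9 of 9 mice.

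Between CP and the other subregions 7934 genes were called, 4037 higher and 3897 lower in CP, and 5887 had the same sign in every mouse. edgeR called 4042 higher and 5080 lower. Of 24 choroid plexus epithelium genes 23 were called higher (camera adjusted p = 6.38e-27, adjusted p = 0.0585 with an estimated correlation), and of 14 ependymal genes 11, with the ciliary regulator Foxj1 at 3.47 (SE 0.14, camera adjusted p = 6.55e-08, adjusted p = 0.0585 with an estimated correlation). All 17 general neuronal genes and all 25 presynaptic genes were called lower, as were 26 of 28 postsynaptic density genes and 15 of 16 excitatory neuron genes. Ribosomal protein genes were higher in 67 of 73 cases, genes of oxidative phosphorylation in 50 of 60 with 3 lower, and lysosomal genes in 21 of 29 with 3 lower, among them Ctsd (3.24, SE 0.05) and Cd63 (4.20, SE 0.08). Set tests called 22 of 36 lists, and none with an estimated correlation, where their adjusted p ran from 0.0585 to 0.247. When CP and the other subregions were swapped within mice, the real assignment called the most of 100, and the highest other called 5598. Without the mouse as a block 7415 genes were called.

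Cdkn2a, the gene of p16, served as a check of the AOI labels. Its signal was near the middle of all genes (percentile 52.7), above the negative probe in 86 of 90 AOIs, with 2 to 85 counts per AOI. At a mean of 1.57 times the negative probe, against 1.52 for the gene median, it lay close to background. The check could therefore miss a difference. The highest of the 90 AOIs was one labelled p16 low, SS of mouse 1151, at 73.6 (6.20 times the negative probe), against at most 33.1 in a p16 high AOI. Over hippocampus and cortex its mean signal was 21.4 in p16 high and 22.0 in p16 low AOIs (log2 difference -0.04, SE 0.11, adjusted p = 0.920, positive in 5 of 10 mice). By subregion the difference was 0.18 (SE 0.23) in CA1, -0.16 (SE 0.18) in CA3, -0.04 (SE 0.14) in MC, -0.18 (SE 0.20) in SS and 0.30 (SE 0.22) in CP, and none passed. A p that misses the threshold does not show that the transcript was equal. Cdkn1a, which encodes p21, another cell cycle inhibitor, differed by -0.11 (SE 0.09) over hippocampus and cortex and did not pass either. Cdkn1a did differ between subregions, with 0.53 (SE 0.16) in CA3 over CA1 (adjusted p = 0.0255, lost without mouse 1151 at 0.0619 and without mouse 1163 at 0.0686, range over all settings 0.00279 to 0.331). In CP over the other subregions it was higher by 0.34 (SE 0.09, adjusted p = 0.00637, 0.0955 with edgeR, range 0.00345 to 0.138).

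Between p16 high and p16 low AOIs of hippocampus and cortex, 77 genes were called and all were higher in p16 high AOIs. The largest difference was in Cpne7, of the calcium-dependent copine family, on chromosome 8 (123117313 to 123135185), with a mean signal of 57.6 against 41.6 (1.38-fold, log2 0.46, SE 0.08, 0.09 to 1.07 in single mice, adjusted p = 0.0081). Hpca, which encodes the neuronal calcium sensor hippocalcin, had 780 against 639 (log2 0.29, SE 0.05, adjusted p = 0.0081). Egr1, an activity-regulated transcription factor gene on chromosome 18 (34861207 to 34864956), had 142 against 117 (log2 0.28, SE 0.06, adjusted p = 0.0303). Others were the peptidase gene Thop1 (0.38, SE 0.08), Mrpl11 of the mitochondrial ribosome (0.36, SE 0.07), Tnks1bp1 (0.34, SE 0.07), Nol4 (0.32, SE 0.06), the tuberous sclerosis gene Tsc2 (0.32, SE 0.07), Tspan13 (0.29, SE 0.06) and the adenylate kinase gene Ak5 (0.27, SE 0.06). These 10 genes were higher in p16 high AOIs in all 10 mice, as the rule for naming them required and the gene plot shows.

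**Figure D3:**
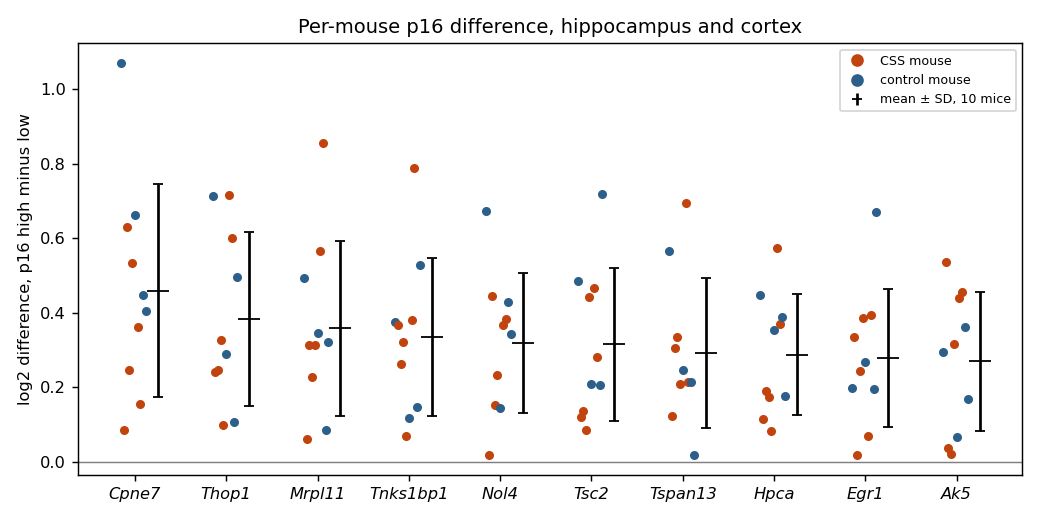
Log2 difference between p16 high and p16 low AOIs of hippocampus and cortex for 10 genes, with a point per mouse (10 mice) and mean ± SD. Each point lies above 0.

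The 77 genes differed by log2 0.19 to 0.46 (median 0.25), and 43 of them had the same sign in all 10 mice. Of all 19962 genes 2828 had an unadjusted p under 0.05, and 227 (1.14%) were separate from 0 in all mice, against 0.195% by chance. Of the 77 calls, 74 lay in the highest quartile of signal and 3 in the next. The median log2 difference over all genes rose with signal, from -0.05 and -0.03 in the 2 lower quartiles to 0.03 and 0.11 in the 2 higher. The gene median over the negative probe was itself higher in p16 high AOIs, by log2 0.047 (9 of 10 mice, exact sign-flip p = 0.0117). With that ratio as a covariate 134 genes were called, 16 of them shared. No gene was called with quantile normalization or with scaling to the 75th percentile, whereas edgeR called 143 higher and 8 lower, 62 of them shared. Without the mouse as a block no gene was called, and with the mouse as a random block over all AOIs 1, Cpne7. The count fell to 0 without control mouse 1151 and without control mouse 1175, to 4 without 1162, 7 without 1170, 9 without 1169 and 10 without 1157, and rose to 123 without 1152, 132 without 1168 and 256 without 1182. Within the 5 mice of deeper counts 6 genes were called, and within the 5 of shallower counts 0. Of 100 swaps of high and low labels within mice the real one called the most, and the highest other called 9.

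Genes of excitatory synapses were higher as sets in p16 high AOIs. Of 16 excitatory neuron genes 14 were above 0 in p16 high AOIs and 3 were called, the glutamate receptor subunits Grin2a (0.27, SE 0.04) and Gria2 (0.22, SE 0.05) and Nrgn (0.21, SE 0.05), with 12 passing when adjusted over the list alone (camera adjusted p = 3.51e-09, adjusted p = 0.101 with an estimated correlation). Of 28 postsynaptic density genes 27 were above 0, 5 were called, including the scaffold gene Dlgap1 (0.22, SE 0.05) and the adhesion gene Nlgn3 (0.24, SE 0.05), and 16 passed over the list alone (camera adjusted p = 8.68e-11, adjusted p = 0.101 with an estimated correlation, 0.483 with quantile normalization). Of 22 immediate early genes 20 were above 0, Egr1 and Junb (0.27, SE 0.06) were called, and 6 passed over the list alone (camera adjusted p = 2.07e-05, adjusted p = 0.101 with an estimated correlation, 0.452 with signal over background as a covariate). The activity-regulated gene Arc, at 0.24 (SE 0.06, adjusted p = 0.0580), was among the members that did not pass. Itpka (0.28, SE 0.06, adjusted p = 0.0314), a CA1 marker in the lists, and Fezf2 (0.35, SE 0.08, adjusted p = 0.0476), a transcription factor of deep cortical layers, were called as well.

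Housekeeping machinery was also higher in p16 high AOIs under the deposited scaling. All 60 genes of oxidative phosphorylation were above 0, with Atp5pb of ATP synthase called (0.22, SE 0.05) and 14 passing over the list alone (camera adjusted p = 1.24e-13, adjusted p = 0.199 with an estimated correlation), and the list turned direction with quantile normalization (adjusted p = 0.447). Of 73 ribosomal protein genes 69 were above 0, none was called and 2 passed over the list alone, with Rps27a at 0.20 (SE 0.05, camera adjusted p = 1.55e-08, adjusted p = 0.199 with an estimated correlation). Quantile normalization turned this list down (adjusted p = 2.82e-09). The presynaptic list (24 of 25 above 0, 0 called, 13 over the list alone, camera adjusted p = 1.55e-08, adjusted p = 0.199 with an estimated correlation) and the general neuronal list (15 of 17 above 0, 0 called, 10 over the list alone, camera adjusted p = 4.12e-06, adjusted p = 0.218 with an estimated correlation, 0.101 without the mouse as a block) turned direction as well. So did the lysosome list (25 of 29 above 0, 0 called, 3 over the list alone, camera adjusted p = 0.0072, adjusted p = 0.241 with an estimated correlation, 0.101 without the block). The unfolded protein list had 24 of 26 genes above 0 and none called, 4 over the list alone (camera adjusted p = 2.71e-04, adjusted p = 0.199 with an estimated correlation).

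Markers of other cells were lower as sets in p16 high AOIs, though no single member was called. Of 18 inhibitory neuron genes 16 were below 0, with the neuropeptide gene Npy at -0.33 (SE 0.09, adjusted p = 0.0922) and Gad1, which makes GABA, at -0.15 (SE 0.06); over the list alone 1 lower and 1 higher gene passed (camera adjusted p = 8.63e-04, adjusted p = 0.199 with an estimated correlation). Of 20 astrocyte genes 15 were below 0, with Gja1 at -0.17 (SE 0.08, camera adjusted p = 0.00722, adjusted p = 0.199 with an estimated correlation), a call lost without mouse 1169 (0.0541). The mural cell list had 9 of 14 below 0, with Acta2 at -0.30 (SE 0.11, camera adjusted p = 0.00722, adjusted p = 0.101 with an estimated correlation). The choroid plexus list had 15 of 24 below 0, with Ttr at -0.32 (SE 0.11, camera adjusted p = 0.00722, adjusted p = 0.138 with an estimated correlation). The oligodendrocyte list had 15 of 20 below 0 (camera adjusted p = 0.00722, adjusted p = 0.390 with an estimated correlation) and lost its call without mouse 1152 (0.0582) or 1175 (0.1002). With signal over background as a covariate it stood in the other direction (0.0890). The list of disease-associated microglia had 14 of 20 below 0 (camera adjusted p = 0.0479, adjusted p = 0.191 with an estimated correlation), a call lost without the mouse as a block (0.0523) and without mouse 1152, 1157, 1162, 1163, 1169, 1170 or 1175 (0.0577 to 0.0845).

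The senescence list was not called between p16 high and p16 low AOIs. Of its 19 genes 10 were above and 9 below 0 (camera adjusted p = 0.727), with Hmgb1 at 0.17 (SE 0.05), Cdkn1b at 0.11 (SE 0.06), Hmgb2 at 0.20 (SE 0.11) and Cdkn1c at 0.20 (SE 0.13), none of them called. Of 48 genes of the senescence-associated secretory phenotype 25 were above 0 (camera adjusted p = 0.140); the median of the list was 0.0046, its mean -0.015 and the direction of its test down. Fgf2 of this list was at 0.40 (SE 0.12, adjusted p = 0.104). Of all 36 lists 15 were called, 9 higher and 6 lower in p16 high AOIs; 0 kept the call with an estimated correlation (adjusted p from 0.101 to 0.390), and fry called 5 of them.

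In CA1, 18 genes were called and all were higher in p16 high AOIs (8 mice, 4 CSS and 4 control). Fezf2 was 1.82-fold higher (mean signal 53.1 against 28.8, log2 0.86, SE 0.16, adjusted p = 0.0078). Further genes with the same sign in 8 of 8 mice were the CA1 marker Spink8 (0.51, SE 0.11), the diacylglycerol kinase Dgki (0.47, SE 0.09), Septin5 (0.47, SE 0.08), the calcium channel gene Cacna1e (0.42, SE 0.08), Cab39 (0.39, SE 0.08), the calcineurin subunit Ppp3r1 (0.34, SE 0.06), Gria2 (0.29, SE 0.06) and Ncdn (0.27, SE 0.06). Of 9 CA1 pyramidal markers 8 were above 0 and Wfs1 (0.45, SE 0.09, 7 of 8 mice) and Spink8 were called, 5 over the list alone (camera adjusted p = 1.73e-06, adjusted p = 0.163 with an estimated correlation). Of 16 excitatory neuron genes 14 were above 0, with Nptx1 (0.41, SE 0.09) and Gria2 called and 11 passing over the list alone (camera adjusted p = 2.15e-09, adjusted p = 0.163 with an estimated correlation).

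The 6 genes called both in CA1 and over hippocampus and cortex compare with 0.530 by chance among genes of like signal (20 bins of mean signal), but the CA1 AOIs are part of the pooled values. Of the 18 CA1 calls 14 were also lower in CA3 than in CA1 (5.21 by chance among genes of like signal), and of the 77 pooled calls 47 were (24.0 by chance). The CA1 AOIs entered both sides of these overlaps as well. The 18 calls changed with scaling: quantile normalization called 5 higher and 4 lower, the 75th percentile 8 higher and 2 lower, and edgeR 81 higher and 22 lower. Without the mouse as a block or with signal over background as a covariate 0 genes were called; that ratio was higher in p16 high AOIs of CA1 by log2 0.096 (6 of 8 mice, exact sign-flip p = 0.0469). Without mouse 1151 the count was 9, without 1152 or 1175 it was 11, without 1163 10, without 1168 5, without 1162 1 (Cpne7, at 0.71, SE 0.11, in all 8 mice together) and without 1182 107. The deeper mice alone gave 47 calls and the shallower 2, Rgs19 and Sst. Genes named only here were chosen after their values were seen. Of 100 label swaps 2, the real one included, called as many genes, and the highest other, which turned mouse 1182 alone, called 44.

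In CA3 no gene was called with limma (8 mice, smallest adjusted p = 0.184, 2654 genes with an unadjusted p under 0.05), whereas edgeR called 55, 51 of them higher in p16 high AOIs. Without CSS mouse 1152 limma called 538 genes, 523 higher. Among 100 swaps the highest count, 626, came from turning mouse 1152 alone. The highest values were those of Galnt16 (0.65, SE 0.14), Arhgef26 (0.75, SE 0.16), Slk (0.65, SE 0.14), Caln1 (0.63, SE 0.14) and Yy1 (0.62, SE 0.13). The lowest were those of the interneuron neuropeptide Npy (-0.88, SE 0.21), Cyp39a1 (-0.91, SE 0.19), the DNA damage kinase Atr (-0.86, SE 0.22), Mkrn3 (-0.73, SE 0.19) and Banf2 (-0.87, SE 0.24), all with adjusted p = 0.184. Sets moved together: all 60 oxidative phosphorylation genes were above 0, 32 passing over the list alone, with Ndufa9 at 0.43 (SE 0.12) and Atp5pb at 0.40 (SE 0.11, camera adjusted p = 4.87e-18, adjusted p = 0.253 with an estimated correlation). All 73 ribosomal protein genes were above 0 (camera adjusted p = 1.67e-07, adjusted p = 0.349 with an estimated correlation), and quantile normalization turned the list down (8.08e-12), as did signal over background as a covariate (0.430). Of 18 inhibitory neuron genes 15 were below 0, with Sst at -0.89 (SE 0.25), and 3 lower and 1 higher gene passed over the list alone (camera adjusted p = 0.0012, adjusted p = 0.253 with an estimated correlation). With signal over background as a covariate this list turned up (0.942). Its mean per mouse was -0.19 ± 0.27 (mean ± SD, 5 of 8 mice below 0, exact sign-flip p = 0.0703). Of 20 oligodendrocyte genes 19 were below 0 (camera adjusted p = 0.0016, adjusted p = 0.253 with an estimated correlation), and of 20 astrocyte genes 17, with Gjb6 at -0.55 (SE 0.22, camera adjusted p = 2.83e-05, adjusted p = 0.253 with an estimated correlation). Per mouse the oligodendrocyte mean was -0.14 ± 0.18 (6 of 8 mice below 0, exact sign-flip p = 0.0625). The astrocyte mean was -0.19 ± 0.18 (6 of 8 mice below 0, exact sign-flip p = 0.0313). The ratio of the gene median to the negative probe was higher in p16 high AOIs of CA3 in 8 of 8 mice (log2 0.114, exact sign-flip p = 0.00781, the smallest possible).

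In the cortex no gene was called in MC (9 mice, smallest adjusted p = 0.913, 996 genes with an unadjusted p under 0.05) or SS (9 mice, 0.945, 898 genes) with limma, and edgeR called 0 in MC and in SS 1, Ttr, lower in p16 high AOIs. Immediate early genes were higher as a set in both. In MC 17 of 22 were above 0, with Egr1 at 0.40 (SE 0.08, mean signal 110 against 83.0), Arc at 0.39 (SE 0.09, 9 of 9 mice) and Junb at 0.44 (SE 0.13), none called and 3 passing over the list alone (camera adjusted p = 3.32e-05, adjusted p = 0.307 with an estimated correlation). In SS 17 of 22 were above 0, with Egr3 at 0.29 (SE 0.09, 9 of 9 mice) and Egr1 at 0.34 (SE 0.11, camera adjusted p = 4.26e-04, adjusted p = 0.119 with an estimated correlation). The mean of the list was 0.15 ± 0.15 in MC (mean ± SD, 8 of 9 mice, exact sign-flip p = 0.0195) and 0.15 ± 0.11 in SS (8 of 9 mice, exact sign-flip p = 0.0078), and the list plot shows it beside the other subregions. In the hippocampal fields together its mean was 0.11 (10 mice, exact sign-flip p = 0.0625), and the difference between cortex and hippocampus was 0.03 (exact sign-flip p = 0.680). The ratio of the gene median to the negative probe differed by log2 0.004 in MC (exact sign-flip p = 0.789) and -0.011 in SS (exact sign-flip p = 0.848).

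**Figure D4:**
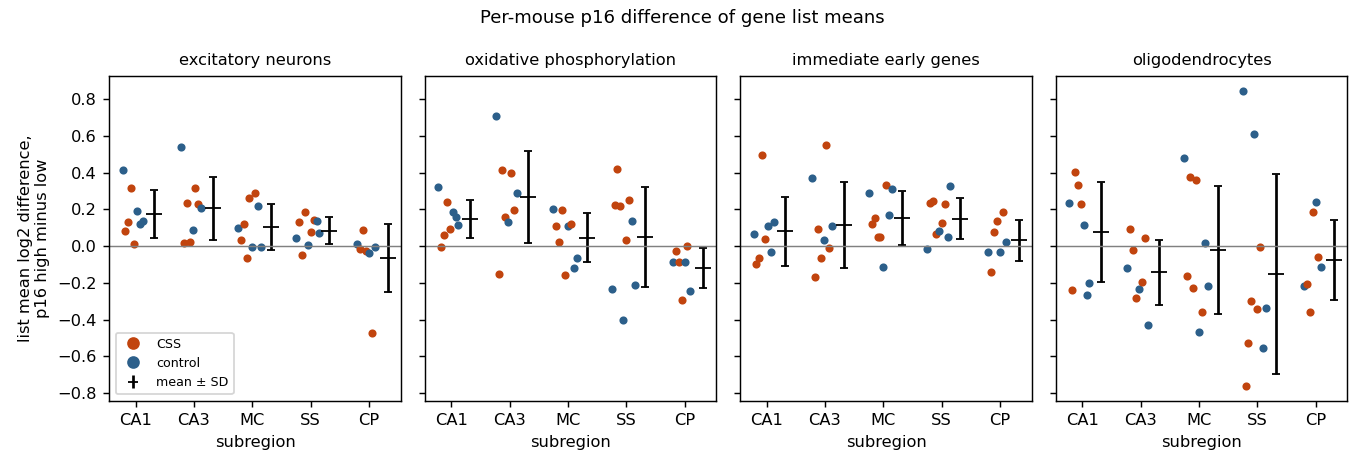
Mean log2 difference between p16 high and p16 low AOIs for 4 gene lists in 5 subregions, with a point per mouse (7 to 9 mice). The oxidative phosphorylation list turned direction with quantile normalization over hippocampus and cortex, in CA1 and in MC; the immediate early, excitatory neuron and postsynaptic lists did not over hippocampus and cortex.

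Excitatory neuron genes were higher as a set in MC (13 of 16 above 0, 0 called, 2 over the list alone, camera adjusted p = 0.00155, adjusted p = 0.307 with an estimated correlation, 0.352 without the mouse as a block), with Grin2a at 0.24 (SE 0.07) and Gria2 at 0.19 (SE 0.06). The range of its adjusted p over all settings was 1.29e-04 to 0.352. Postsynaptic density genes were higher there too (21 of 28 above 0, 3 over the list alone, camera adjusted p = 0.00524, adjusted p = 0.307 with an estimated correlation, 0.387 without the block), a call lost without mouse 1170 (0.0844). Oligodendrocyte genes were lower in p16 high AOIs of SS (17 of 20 below 0, 0 called), with the myelin gene Mag at -0.57 (SE 0.14) and Mobp at -0.37 (SE 0.16, camera adjusted p = 2.71e-04, adjusted p = 0.851 with an estimated correlation), a call lost without mouse 1152 (0.118). The list mean per mouse was -0.15 ± 0.54 (mean ± SD, 7 of 9 mice below 0, highest 0.84, exact 2-sided sign-flip p = 0.410). Choroid plexus genes were also lower in SS (15 of 24 below 0), with Ttr at -1.05 (SE 0.26, 8 of 9 mice, camera adjusted p = 0.0124, adjusted p = 0.119 with an estimated correlation), lost without mouse 1169 (0.0944). Among single genes with high moderated t in MC were Trim28 (0.50, SE 0.11), Atp2b1 (0.33, SE 0.08), a plasma membrane calcium pump, and Igfbp4 (0.62, SE 0.15), and in SS H4c11 (0.47, SE 0.12) and Dcun1d3 (0.54, SE 0.14), none called. Of 100 swaps the highest called 10 genes in MC and 4 in SS.

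In the choroid plexus no gene was called between p16 high and p16 low AOIs (7 mice, limma smallest adjusted p = 0.889, 1046 genes with an unadjusted p under 0.05), and edgeR called 6: Cox8b, Rgs19, Itgb2, Cntn1, Acmsd and Marveld1, most of them named only after their values were seen. Without mouse 1170 limma called Cox8b and Rgs19. The neural adhesion gene Cntn1 was at -0.37 (SE 0.08, 7 of 7 mice), Dlgap1 at -0.46 (SE 0.12), Klf10 at 0.61 (SE 0.16) and the ciliary gene Deup1 at 0.73 (SE 0.19), all with adjusted p = 0.889. Here oxidative phosphorylation was lower in p16 high AOIs: 57 of 60 genes were below 0, with Ndufa3 at -0.23 (SE 0.07, 7 of 7 mice) and Cox6b1 at -0.31 (SE 0.09, camera adjusted p = 8.70e-12, adjusted p = 0.670 with an estimated correlation). Of 29 lysosomal genes 24 were below 0, with Npc2 at -0.27 (SE 0.08, camera adjusted p = 6.24e-06, adjusted p = 0.670 with an estimated correlation, 0.0962 without the mouse as a block), and of 24 choroid plexus epithelium genes 21, with Kl at -0.22 (SE 0.07) and Ttr at -0.14 (SE 0.06, 7 of 7 mice, camera adjusted p = 8.69e-05, adjusted p = 0.670 with an estimated correlation, 0.579 without the block). The mean of the oxidative phosphorylation list was below 0 in 7 of 7 mice (-0.12, exact sign-flip p = 0.0156, the smallest possible). The ratio of the gene median to the negative probe was higher in p16 high AOIs (log2 0.041, 6 of 7 mice, exact sign-flip p = 0.0313). Of 64 swaps the highest called 1 gene.

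Between CSS and control mice no gene was called over hippocampus and cortex (limma, 6 against 4 mice, smallest adjusted p = 0.9997, 391 genes with an unadjusted p under 0.05, edgeR called 0 in the 6 mice with every AOI). The lowest moderated t was that of Npas4, an activity-dependent transcription factor gene, with a mean signal of 33.6 in CSS mice and 48.8 in controls (log2 -0.53, SE 0.12), and groups that did not overlap. Vip, the gene of an interneuron neuropeptide, was at -0.39 (SE 0.13). The highest was that of Ptgds, which encodes prostaglandin D synthase (0.53, SE 0.15, 88.4 against 61.1), followed by Gm7102 (0.49, SE 0.14), C8g (0.44, SE 0.13) and Tnfsf13 (0.35, SE 0.11). With genes above the median signal alone Npas4 and Gm7102 were called. Cdkn2a had a mean signal of 22.6 in CSS mice and 21.7 in controls (0.06, SE 0.11), and Cdkn1a differed by -0.14 (SE 0.11). In all, 80 genes (0.401%) had groups that did not overlap, against 0.952% by chance.

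None of the lists on senescence and stress was called between CSS and control mice. Of 19 senescence genes 11 were below 0 (camera adjusted p = 0.499), with Cdkn1c at -0.33 (SE 0.12), and of 48 secretory phenotype genes 31 were above 0 (adjusted p = 0.521). Of 24 glucocorticoid receptor targets 14 were above 0 (adjusted p = 0.345), with Ddit4 at 0.23 (SE 0.12) and Arrdc2 at 0.26 (SE 0.12). Of 22 immediate early genes 11 were below 0 (0.643), and of 20 microglial genes 11 (0.976). Oligodendrocyte genes were higher in CSS mice as a set, 16 of 20 above 0 and none called, with Cldn11 at 0.27 (SE 0.13) and Mal at 0.26 (SE 0.12, camera adjusted p = 0.0070, adjusted p = 0.983 with an estimated correlation). This call was lost without mouse 1151 (0.345) or 1162 (0.278) and within the deeper (0.0535) and shallower mice (0.0546), and the list mean differed by 0.089 (exact permutation p = 0.281). Within the 5 shallower mice 84 genes were called, 76 of them lower in CSS mice. The controls among these, 1151 and 1182, had the highest gene medians over the negative probe of all 10 mice in hippocampus and cortex (1.665 and 1.669). The CSS mice among them had 1.53 to 1.61. Of 100 assignments of mice to groups one of 1152, 1163, 1169 and 1175 as controls called 2175 genes.

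In p16 high AOIs alone no gene was called (limma smallest adjusted p = 0.9998, 475 genes with an unadjusted p under 0.05, edgeR 0). Ptgds was at 0.68 (SE 0.17), Smim22 at 0.96 (SE 0.25), Vip at -0.71 (SE 0.19) and Npas4 at -0.57 (SE 0.16). In p16 low AOIs limma also called 0 (smallest adjusted p = 0.752, 535 genes with an unadjusted p under 0.05, edgeR 0), with C8g at 0.74 (SE 0.17), Tnfsf13 at 0.59 (SE 0.14) and Rgs14 at 0.59 (SE 0.15). Without control mouse 1175 Sst was called there. The oligodendrocyte list was higher in p16 low AOIs of CSS mice (19 of 20 above 0, camera adjusted p = 6.04e-04, adjusted p = 0.973 with an estimated correlation), lost without mouse 1151 (0.586) or 1162 (0.0554).

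By subregion, limma called no gene between CSS and control mice in CA1 (568 genes with an unadjusted p under 0.05, edgeR 3: Slc13a5, Gm11596 and Ptgds), CA3 (582, edgeR 5: Acad10, Olfr860, Rgs19, Smim22 and Gm11596), MC (552, edgeR 0), SS (730, edgeR 2: Hba-a1 and Hbb-b1) or CP (655, edgeR 4: Itgb2, Olfr706, Hs1bp3 and S1pr2). These edgeR fits had fewer mice than limma (8 in CA1, 8 in CA3, 9 in MC, 9 in SS and 7 in CP), the one in SS being without mouse 1163. Several of these genes were named only after their values were seen. In CA1 Ptgds was at 0.83 (SE 0.25) and Npas4 at -0.75 (SE 0.20). In CA3 Smim22, which encodes a small membrane protein, had 199 against 82.5 (log2 1.26, SE 0.27, adjusted p = 0.588) and was called without mouse 1152. Oligodendrocyte genes were higher in CSS mice in CA3 (16 of 20 above 0, 1 over the list alone, Cldn11 at 0.67, SE 0.21, camera adjusted p = 4.02e-05, adjusted p = 0.540 with an estimated correlation), with a list mean 0.21 higher (exact permutation p = 0.0238). In CA1 the list (17 of 20 above 0, camera adjusted p = 0.0021, adjusted p = 0.999 with an estimated correlation) lost its call without mouse 1151 (0.0591), 1162 (0.0516) or 1170 (0.296). In MC the corticotropin-releasing hormone gene Crh was at -0.63 (SE 0.18) and Fam174b at 0.65 (SE 0.16). In CP of 5 CSS and 4 control mice the clock output gene Dbp had 155 against 88.2 (0.80, SE 0.19) and was called with quantile normalization alone.

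In SS the haemoglobin genes were the ones that stood out between the groups. Hba-a1, on chromosome 11 (32283672 to 32284486), had a mean signal of 38.8 in CSS mice and 101 in controls (log2 -1.36, SE 0.28, adjusted p = 0.283), and Hbb-b1 28.7 against 66.4 (-1.18, SE 0.23, adjusted p = 0.156). In both, 5 of 6 CSS mice lay below every control, the exception being mouse 1163, as the haemoglobin plot shows. Both genes passed without mouse 1163 and without mouse 1175, and with edgeR, which left out mouse 1163 as well because it had no p16 high AOI in SS. The adjusted p of Hbb-b1 ranged from 8.85e-10 to 0.99995 over all settings. Of the 6 genes of the blood list 5 were below 0, 2 passing over the list alone (camera adjusted p = 3.31e-06, adjusted p = 0.0213 with an estimated correlation, fry 0.152). The list mean was lower by 0.51 in CSS mice (exact permutation p = 0.0190). The difference between SS and the mean of CA1, CA3 and MC in this list was -0.48 (exact permutation p = 0.0571). Gm7102 (0.97, SE 0.22), Itga2 (0.97, SE 0.23) and the clock and glucocorticoid target gene Per1 (0.50, SE 0.15) were the highest named values in SS. The haemoglobin paralogs are so alike that their probes may share transcripts.

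**Figure D5:**
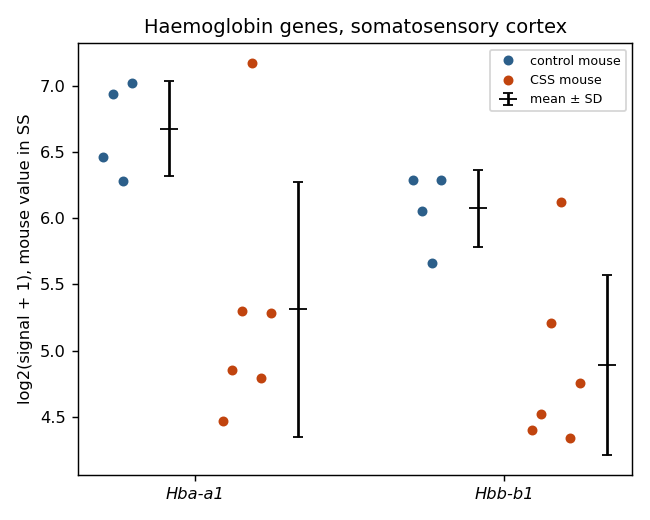
Signal of Hba-a1 and Hbb-b1 in the somatosensory cortex of 6 CSS and 4 control mice, with a point per mouse. The direction did not turn under another scaling.

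The difference of the p16 effect between CSS and control mice was tested directly, and no gene was called (limma, smallest adjusted p = 0.998, 663 genes with an unadjusted p under 0.05, edgeR 0). Smim22 had the highest moderated t (log2 0.65, SE 0.16), followed by Tob1 (0.62, SE 0.16), and Gtse1 was at 0.96 (SE 0.27) and Pdlim2 at -0.72 (SE 0.21). General neuronal genes had a larger p16 effect in CSS mice, with 14 of 17 above 0 (camera adjusted p = 9.33e-05, adjusted p = 0.774 with an estimated correlation). Per mouse, the mean p16 effect of this list was 0.18 ± 0.14 in CSS mice and 0.02 ± 0.16 in controls (exact permutation p = 0.143).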

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

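Of the tests below, that of the range over 4 glial and vascular lists, the comparison of oxidative phosphorylation genes with genes of matched signal, that of inhibitory neuron genes, those between the hippocampal fields and the choroid plexus, those within mice of deeper or shallower counts, and edgeR were chosen only after the result was seen. Comparisons of general neuronal, ribosomal and mural genes with genes of matched signal were not set beforehand either.

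Single AOIs stood far from the others of their group in 3 of 72 groups and measures, where chance marks about 1 in 20, or 3.6. In motor cortex p16 high AOIs of CSS mice the gene median stood 1.48 times above the negative probe in mouse 1170, against 1.27 to 1.34 in the 5 other mice. The Cdkn2a signal in choroid plexus p16 high AOIs of CSS mice was 14.7 in mouse 1163 and 22.067 to 24.7 in the 4 others. The Cdkn1a signal in motor cortex p16 low AOIs of CSS mice was 18.1 in mouse 1152 and 27.6 to 30.6 in the 4 others.

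Camera called a difference of the p16 effect between groups for some gene lists. Between CSS and control mice these were general neuronal genes (adjusted p = 9.33e-05, 0.774 with an estimated correlation) and oxidative phosphorylation genes (camera adjusted p = 0.0203, 0.879 with an estimated correlation). The call of the latter list was lost without mouse 1157 (0.249), 1162 (0.193), 1168 (0.514), 1169 (0.310), 1170 (0.124) or 1182 (0.371). Per mouse neither was supported: the mean p16 effect of the general neuronal list was 0.18 in CSS mice and 0.021 in controls (6 against 4 mice, exact 2-sided permutation p = 0.143), and that of the oxidative phosphorylation list 0.14 and 0.08 (exact permutation p = 0.400). Between the hippocampal fields and the choroid plexus of the same 7 mice it differed by 0.32 for oxidative phosphorylation genes (6 of 7 mice, exact 2-sided sign-flip p = 0.0313). For lysosomal genes it differed by 0.23 (7 of 7 mice, exact sign-flip p = 0.0156, the smallest possible) and for ribosomal protein genes by 0.20 (6 of 7 mice, exact sign-flip p = 0.0313). These directions hold at the deposited scaling, since quantile normalization turned the ribosomal list in CA1 (adjusted p = 1.69e-05), CA3 (8.08e-12) and CP (0.604), the oxidative phosphorylation list in CA1 (0.381) and the lysosomal list in CA3 (0.299).

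Genes higher in p16 high AOIs of hippocampus and cortex: all 77 calls were higher there, 74 of them in the highest quartile of signal, while the gene median over the negative probe was also higher. If that ratio were the whole cause, genes of every kind would be higher alike. Excitatory neuron genes exceeded genes of matched signal by 0.035 ± 0.043 (mean ± SD, 8 of 10 mice, exact 2-sided sign-flip p = 0.0293). General neuronal genes did not (-0.020 ± 0.088, 5 of 10 mice above 0, exact sign-flip p = 0.486). Matching used the mean over all 90 AOIs, choroid plexus included, where excitatory neuron genes were lower. The matched genes may thus have had lower signal in hippocampus and cortex, where the difference rose with signal. Ribosomal and mural genes lay below matched genes (-0.058 and -0.089, 8 and 9 of 10 mice, exact sign-flip p = 0.00977 for each). Oxidative phosphorylation genes did not pass (-0.014, exact sign-flip p = 0.396). Matching limits these too, so the excess cannot decide and the ratio stays open. With quantile normalization limma called 0 genes in all (1189 at an unadjusted p under 0.05), against 151 with edgeR. A lower share of all glial and vascular cells would lower their markers alike and stays open, since the range of 0.14 between the highest of 4 lists against matched genes, endothelial genes (0.011 ± 0.055), and the lowest, astrocyte genes (-0.13 ± 0.14), gave an exact sign-flip p of 0.154 with the range taken anew in each flip, and a lower share of astrocytes or inhibitory neurons (-0.14) alone stays open too. A difference between p16 high and low cells as labelled is the biological explanation and was not tested apart from these, since Cdkn2a itself did not pass and how p16 was assigned is not given.

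Immediate early genes higher in p16 high AOIs of the cortex: the list exceeded genes of matched signal in motor and somatosensory cortex by 0.12 ± 0.10 (mean ± SD, 10 of 10 mice, exact 2-sided sign-flip p = 0.00195, the smallest possible). Matching used the mean over all AOIs, choroid plexus included. The ratio of the gene median to the negative probe itself differed little here, by log2 0.004 in MC (exact sign-flip p = 0.789) and -0.011 in SS (exact sign-flip p = 0.848). Together these values argue against signal over background as the whole cause. A higher share of excitatory neurons in p16 high AOIs stays open, since the list did not exceed the excitatory neuron list by more than its spread (0.043, 6 of 10 mice, exact sign-flip p = 0.342). Greater neuronal activity around p16 high cells is a hypothesis, and no activity measure other than these transcripts was available to test it. The camera call of the list was lost with an estimated correlation in both MC (adjusted p = 0.307) and SS (adjusted p = 0.119).

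Haemoglobin genes lower in the somatosensory cortex of CSS mice: Hba-a1 and Hbb-b1 were lower in 5 of 6 CSS mice than in every control. A single animal as the cause is argued against, because the blood list kept its call without any one of the 10 mice, with a highest camera adjusted p of 3.65e-04 without mouse 1170. Less blood left in the captured tissue would lower both genes alike and stays open, since their log ratio gave an exact 2-sided permutation p of 0.424 (6 against 4 mice), and a p above the threshold does not show equality. The list mean was lower by 0.54 within the 3 CSS and 2 control mice of deeper counts (exact permutation p = 0.1, the smallest possible) and by 0.47 within the 3 and 2 of shallower counts (exact permutation p = 0.3). An effect of stress on the blood content of this region, the explanation the groups name, was not tested apart from a difference in how the brains were drained of blood, which the labels do not give.

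Swapping labels among the same mice tested whether chance could give as many calls. For the pooled p16 comparison only the real assignment of 100 gave as many (77 genes, highest other 9). The same held for CA3 against CA1 (2983 genes, highest other 1106) and CP against the other subregions (7934 genes, highest other 5598). Such swaps detect any shift shared by the mice. In the pooled p16 comparison that includes the higher ratio of gene median to negative probe (9 of 10 mice). For p16 in CA1 (18 genes) 2 of 100 gave as many, the real assignment included, and 15 of the others called some gene. The other assignment with as many, with mouse 1182 alone turned, gave 44, and leaving out that mouse gave 107. No correction was made for the number of comparisons, so chance is not excluded in CA1. Where limma called 0 genes every assignment gives at least as many, so that the swaps decide nothing about chance and are given as values. For p16 this was so in CA3 (100 of 100, highest other 626, with mouse 1152 alone turned, where leaving it out gave 538, and 2654 genes at an unadjusted p under 0.05, edgeR 55), MC (100 of 100, highest other 10, 996 genes, edgeR 0), SS (100 of 100, highest other 4, 898 genes, edgeR 1) and CP (64 of 64, highest other 1, 1046 genes, edgeR 6). For CSS against control it was so over hippocampus and cortex (100 of 100, highest other 2175, 391 genes, edgeR 0), in p16 high AOIs (highest other 323, 475 genes, edgeR 0), p16 low AOIs (6, 535 genes, edgeR 0), CA1 (4, 568 genes, edgeR 3), CA3 (2, 582 genes, edgeR 5), MC (1480, 552 genes, edgeR 0), SS (18, 730 genes, edgeR 2), CP (6, 655 genes, edgeR 4) and for the difference of the p16 effect (2, 663 genes, edgeR 0). The assignments with 2175 and 1480 calls, which both had mice 1152, 1169 and 1175 as controls, point to a structure of the samples other than the stress groups. Neither followed the counts, since mouse 1169 was of shallower counts and mice 1152 and 1175 of deeper ones. The assignment with 1480 calls in MC, which added mouse 1157, followed signal over background, as these 4 mice had the 4 lowest gene medians over the negative probe in MC (1.22 to 1.28, against 1.31 or more in the others), while for the one with 2175 calls mice 1163 and 1169 ranked 7 and 6 from the lowest of 10.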

How the results depend on the processing

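edgeR, scaling to the 75th percentile, signal over background as a covariate, the depth block and the fits within mice of deeper or shallower counts were chosen only after the results were seen. The CA1 and CA3 pyramidal lists in CA3 against CA1, the choroid plexus list in CP against the other subregions and the blood list for stress in SS kept their direction and call with quantile normalization, with 75th percentile scaling and without any 1 animal. Of called named genes, none turned direction under any setting, 2836 comparisons with another setting kept the call and 361 lost it. Of called lists 1476 such comparisons kept the call, 435 lost it and 28 turned. Of lists that were not called 383 became called in the same direction and 76 were called in the other direction. With the estimated correlation 101 list calls were lost, that of the choroid plexus markers (adjusted p = 0.0585) among them, and 4 kept. With fry 58 were lost, that of the blood list in SS (0.152) among them, and 47 kept. Depth limits the data: 6 to 82 counts for the median gene, and 22.7% of values at or below the negative probe. Except where said, the cause of a change was not tested.

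Counts of called genes are given with the higher and lower ones in brackets where both occurred. With log2(signal + 10) they were 129 (128 and 1) for p16 over hippocampus and cortex, 86 (79 and 7) in CA1 and 2 for stress in SS. With genes above the median signal alone, where fewer genes are adjusted for, they were 265 (264 and 1), 155 (151 and 4) in CA1, and for stress 2 over hippocampus and cortex, 1 in CA3 (Smim22) and 3 in SS (Hbb-b1, Hba-a1 and Gm7102). Quantile normalization gave 0 (limma, 1189 genes at an unadjusted p under 0.05) and in CA1 9 (5 and 4), and for stress 1 in CA3 (Smim22) and 1 in CP (Dbp). The 75th percentile gave 0 (limma, 2460) and in CA1 10 (8 and 2), and for stress 1 in p16 high AOIs (Ptgds), 2 in CA3 (Smim22 and Ptgds) and 1 in SS (Hbb-b1). edgeR gave 151 (143 and 8), in CA1 103 (81 and 22), CA3 55 (51 and 4), SS 1 and CP 6 (2 and 4) for p16, and for stress, in the mice with every AOI, 3 in CA1, 5 in CA3, 2 in SS (without mouse 1163) and 4 in CP. The covariate gave 134 (121 and 13), and 0 in CA1 (limma, 1782). Within deeper mice p16 gave 6 and in CA1 47 (41 and 6), and stress 1 in p16 high AOIs (Rgs19), 3 in CA1 (Rgs19, LOC118568632 and Ptgds), 3 in MC (Gm6958, LOC118568632 and Gm10058) and 2 in SS (Hbb-b1 and Hba-a1). Within shallower mice p16 gave 0 (limma, 1811), in CA1 2 and in CP 8 (3 and 5), and stress 84 (8 and 76), in p16 high AOIs 3 (Smim22, Naip6 and Phrf1), in p16 low AOIs 36 (4 and 32), in CA1 2 (Tcirg1 and Gng3), in CA3 1 (Smim22), in SS 3 (Smim22, Hbb-b1 and Gm7102), for the difference of the p16 effect 1 (Sst) and for CA3 against CA1 1141. Genes named here by their small count were chosen after their values were seen. The depth block moved no count.

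The mouse as a block changed the p16 calls. Without the block limma called 0 genes over hippocampus and cortex (918 at an unadjusted p under 0.05) and 0 in CA1 (1140), and with the mouse as a random block 1 (Cpne7) over hippocampus and cortex. Of the list calls from paired comparisons 22 were lost without the block, 74 kept, and 1 list became called. The block moved no other count of genes by over 1.5 times. Without 1 animal the counts ran from 0 (without 1151, with 2333 at an unadjusted p under 0.05, or 1175, with 2568) to 256 (without 1182) for p16 over hippocampus and cortex, 1 (without 1162) to 107 (without 1182) in CA1, 0 to 538 (without 1152) in CA3 and 0 to 2 (without 1170) in CP. For stress they ran from 0 to 1 (Sst, without 1175) in p16 low AOIs, 0 to 1 (Smim22, without 1152) in CA3 and 0 to 2 (without 1163 or 1175) in SS, and they stayed at 0 in the other stress comparisons.

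Lists that turned are given by adjusted p in the other direction. Quantile normalization, which forces the same distribution on every AOI, turned called lists for reasons not tested. Over hippocampus and cortex they were general neuronal 0.661, presynaptic 0.409, oxidative phosphorylation 0.447, ribosomal 2.82e-09, lysosomal 0.409, in CA1 general neuronal 0.0376, presynaptic 0.106, oxidative phosphorylation 0.381, ribosomal 1.69e-05, unfolded protein 0.905, in CA3 presynaptic 0.479, ribosomal 8.08e-12, lysosomal 0.299, in MC oxidative phosphorylation 0.962, in CP ribosomal 0.604 and for CA3 against CA1 ribosomal 0.595. The covariate turned oligodendrocyte 0.089 over hippocampus and cortex, immediate early 0.049955, oligodendrocyte precursor 0.55, inhibitory neuron 0.942, CA3 pyramidal 0.0149, presynaptic 0.447, ribosomal 0.43, unfolded protein 0.942, lysosomal 0.221 in CA3 and blood 0.771 in CP. In CP against the other subregions fry, which compares with no other genes, called astrocyte (2.31e-04) and oligodendrocyte lists (3.99e-05) higher. With genes above the median signal alone the fibroblast list turned for stress in CA1 (0.0143).

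Within deeper mice (3 CSS and 2 control) lists that were not called in all mice were called in the other direction for stress, higher in CSS mice unless said: over hippocampus and cortex postsynaptic 0.0041, unfolded protein 0.00441, in p16 high AOIs postsynaptic 0.00843, unfolded protein 0.00843, lysosomal 0.00843, in p16 low AOIs proliferation 0.0407, unfolded protein 0.0128 (the first lower), in CA1 postsynaptic 0.00226, in CA3 unfolded protein 0.0363, in MC endothelial 0.0446, postsynaptic 0.0449, oxidative phosphorylation 2.22e-04, unfolded protein 0.0109 (the first lower), in SS leukocyte 0.00163, postsynaptic 0.0436, oxidative phosphorylation 0.00526, ribosomal 1.02e-05 (the first lower) and in CP blood 1.42e-04. Within shallower mice (3 CSS and 2 control) the lists that turned were lower in CSS mice: over hippocampus and cortex general neuronal 1.56e-05, presynaptic 1.56e-05, oxidative phosphorylation 1.86e-12, ribosomal 8.83e-10, lysosomal 0.0023, in p16 high AOIs general neuronal 0.00159, presynaptic 2.34e-04, oxidative phosphorylation 1.57e-10, ribosomal 8.76e-09, in p16 low AOIs excitatory 6.92e-04, postsynaptic 4.34e-07, presynaptic 2.35e-08, oxidative phosphorylation 5.72e-10, ribosomal 1.41e-08, in CA1 general neuronal 1.03e-04, presynaptic 4.80e-07, oxidative phosphorylation 1.13e-05, ribosomal 9.91e-10, lysosomal 0.0174, in CA3 general neuronal 0.00293, excitatory 0.0237, postsynaptic 0.00583, presynaptic 0.00407, oxidative phosphorylation 3.66e-05, ribosomal 1.71e-06 and in MC ribosomal 0.00432. For p16, CP ribosomal 0.953 turned up and SS presynaptic 0.871 down. Controls 1151 and 1182 of the shallower mice had the highest gene medians over the negative probe. The part of that ratio in the turned stress lists was not tested.

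Stress lists also turned without control mouse 1175, and then were lower in CSS mice, apart from the 2 exceptions named. Mouse 1175 had the lowest gene median over the negative probe in hippocampus and cortex (1.29), and the part of that ratio was not tested. Their adjusted p over the fits that leave out 1 mouse, in whichever direction, ran as follows. Over hippocampus and cortex: general neuronal 1.95e-04 to 0.994, postsynaptic 5.76e-06 to 0.994, presynaptic 3.13e-04 to 0.994, oxidative phosphorylation 1.24e-10 to 0.994, ribosomal 8.12e-08 to 0.947, lysosomal 0.00433 to 0.994 (the postsynaptic list turned not without 1175 but without 1151, at 0.0329). In p16 high AOIs: presynaptic 0.0121 to 0.959, oxidative phosphorylation 2.53e-06 to 0.99964, ribosomal 2.53e-06 to 0.99964. In p16 low AOIs: excitatory 0.0232 to 0.996, postsynaptic 9.40e-06 to 0.926, presynaptic 1.49e-06 to 0.94, oxidative phosphorylation 1.49e-12 to 0.965, ribosomal 1.06e-07 to 0.919, lysosomal 0.0188 to 0.886. In CA1: general neuronal 0.0113 to 0.907, presynaptic 0.00151 to 0.92, oxidative phosphorylation 7.37e-05 to 0.849, ribosomal 1.14e-05 to 0.986. In CA3: general neuronal 0.00392 to 0.804, postsynaptic 2.84e-04 to 0.632, oxidative phosphorylation 1.89e-10 to 0.132, ribosomal 6.15e-08 to 0.616 (the oxidative phosphorylation list, called in all mice, turned without 1175 at 0.00612 and lost its call without 1157 at 0.0759 and 1162 at 0.132). In MC: ribosomal 1.72e-04 to 0.99. In SS: ribosomal 4.70e-06 to 0.977 (turned not without 1175 but without 1151 at 0.0101 and without 1182 at 0.0396). In CP: oxidative phosphorylation 0.00236 to 0.926, ribosomal 3.52e-06 to 0.977, lysosomal 0.017 to 0.979.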

Other observations

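The tests in this part were set before the data were examined, apart from signal over background as a covariate, which was chosen only after the results were seen.

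Beside epithelial genes, the choroid plexus carried higher signal of genes listed as markers of vessels, stroma and immune functions. Which cells of the plexus expressed them was not tested. Igfbp2 and Igf2, named above among its highest genes, belong to the fibroblast list. Of 19 endothelial genes 13 were called higher than in hippocampus and cortex and 1 lower, among them Bsg (log2 3.35, SE 0.04, 9 of 9 mice), Eng (1.78, SE 0.13) and the glucose transporter Slc2a1 (1.21, SE 0.09, camera adjusted p = 9.30e-06, adjusted p = 0.0585 with an estimated correlation). Of 18 fibroblast and meningeal genes 13 were called higher and 2 lower, with Mgp, an inhibitor of calcification, at 3.78 (SE 0.13) and Ptgds at 3.35 (SE 0.11, camera adjusted p = 4.81e-07, adjusted p = 0.0585 with an estimated correlation). Of 20 genes of antigen presentation and complement 12 were called, all higher, including B2m (1.61, SE 0.06), the class I gene H2-K1 (2.26, SE 0.10) and Cd74 of the class II pathway (1.89, SE 0.13, camera adjusted p = 7.45e-06, adjusted p = 0.101 with an estimated correlation). Of 28 interferon response genes 9 were called, all higher, with Ifi27 at 3.23 (SE 0.09) and Bst2 at 2.27 (SE 0.10, camera adjusted p = 0.0235, adjusted p = 0.101 with an estimated correlation). Of 26 genes of the unfolded protein and heat shock response 14 were called higher and 7 lower, and the higher ones included the endoplasmic reticulum chaperone genes Hspa5 (1.90, SE 0.07), Hsp90b1 (1.78, SE 0.06) and Pdia4 (2.33, SE 0.09, camera adjusted p = 0.00148, adjusted p = 0.0780 with an estimated correlation). The cell cycle inhibitor gene Cdkn1c was at 4.05 (SE 0.12, 9 of 9 mice, mean signal 349 against 20.04). The list of 20 microglial genes was not called (camera adjusted p = 0.732).

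Genes of the stress hormone response differed between the hippocampal fields in both directions. Of 24 glucocorticoid receptor targets 3 were called higher and 5 lower in CA3 than in CA1 (camera adjusted p = 0.942). Nr3c1, the gene of the glucocorticoid receptor, was lower in CA3 (-1.26, SE 0.10, mean signal 71.2 against 172), as were Zbtb16 (-1.16, SE 0.12) and Per1 (-1.03, SE 0.10), and Sgk1, which encodes a kinase, was higher (1.02, SE 0.11), each in 10 of 10 mice. Of 18 reactive astrocyte genes 2 were called, both higher in CA3, Cd109 (1.07, SE 0.16) and the filament gene Gfap (0.57, SE 0.14, camera adjusted p = 0.0425, adjusted p = 0.114 with an estimated correlation). That list lost its call without mouse 1151 (0.0532), 1152 (0.0604), 1162 (0.0555), 1163 (0.0638), 1175 (0.0516) or 1182 (0.0529). The oligodendrocyte lineage gene Olig1 was at 0.79 (SE 0.12). The retinoblastoma gene Rb1 was lower in CA3 (-0.67, SE 0.12, 10 of 10 mice), as was Igfbp4 (-1.87, SE 0.14), while Fgf2 was higher (0.78, SE 0.18). Of 73 ribosomal protein genes 12 were called lower and 0 higher in CA3 (15 lower over the list alone), with Rpl3 at -0.50 (SE 0.08) and Rps27 at -0.54 (SE 0.09, camera adjusted p = 2.51e-04, adjusted p = 0.548 with an estimated correlation), and quantile normalization turned the direction of this list (adjusted p = 0.595). Ttr was higher in CA3 by 3.36 (SE 0.30, 9 of 10 mice), beside 1 other called gene of the choroid plexus list, Kl, which was lower (-1.03, SE 0.16).

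Among the comparisons of p16 high and p16 low AOIs, further lists were called without a called member. In CA1 blood genes were lower, 6 of 6 below 0 (2 over the list alone, camera adjusted p = 0.00262, adjusted p = 0.181 with an estimated correlation), a call lost without mouse 1182 (0.0907). In CP blood genes were also lower, 6 of 6 (camera adjusted p = 0.0145, adjusted p = 0.670 with an estimated correlation, 0.0773 without the mouse as a block), a call lost without mouse 1157 (0.373) or 1170 (0.126), and with signal over background as a covariate the list turned up (0.771). In CP 17 of 20 genes of antigen presentation and complement were above 0 (camera adjusted p = 0.0199, adjusted p = 0.695 with an estimated correlation, 0.0967 without the block), a call lost without mouse 1152 (0.151), 1170 (0.431) or 1175 (0.0703). In CA3 microglial genes were lower, 14 of 20 below 0 (camera adjusted p = 0.0115, adjusted p = 0.253 with an estimated correlation). Between CSS and control mice, blood genes were lower in p16 low AOIs of hippocampus and cortex, 5 of 6 below 0 (1 over the list alone, camera adjusted p = 0.0139, adjusted p = 0.630 with an estimated correlation), a call lost without mouse 1162 (0.181), 1169 (0.1496), 1175 (0.157) or 1182 (0.435). Of 60 oxidative phosphorylation genes 51 were above 0 in CA3 of CSS mice (camera adjusted p = 0.0123, adjusted p = 0.955 with an estimated correlation), a direction that turned without control mouse 1175 (adjusted p = 0.00612) and a call lost without mouse 1157 (0.0759) or 1162 (0.132).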
